A study of Homo sapiens with 16 samples.

How the data were processed

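MCF-7 cells were assayed after E2 or vehicle by FAIRE and by chromatin immunoprecipitation for Pol II and 6 histone marks, with 1 library per assay and treatment (16 libraries). Groups were taken from the sample titles. Per the labels' protocols, DNA was amplified by 15 cycles of PCR and fragments of 200 to 300 bp were sequenced.

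The deposited files list positions with a signal value per position, which is a whole-number peak height set by the authors. The genome build is hg18, per the submitters' processing notes. The aligner, the peak caller, its control and threshold, the scaling between libraries and the sequencing depth are not given in the sources used here. There is 1 list for each library. No value was below 7 or above 200 in any list. Heights were used to describe, rank and filter positions and for ratios at shared positions, which are not corrected for depth.

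The design set before the data were examined took positions as regions and counted an overlap of at least 1 bp as shared. The files hold peak tops with median widths of 7 to 17 bp, so positions within 1 kb, an alternative listed at the same time, are reported as the main values, and the 1 bp values stand beside them or among the alternatives. Shares carry Clopper-Pearson 95% intervals. PCR reads are not independent molecules, so these cover counting error only. Random expectation came from 100 placements of the same positions within their own chromosomes, up to the last position seen in the lists. Heights were compared at positions matched 1 to 1 within 1 kb, as a median log2 ratio with an order-statistic interval.

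Treatment-only positions were those with no position of the other treatment within 1 kb. For each pair of assays the odds ratio compared the same with the opposite direction, and its interval came from 1000 resamples of 10 Mb blocks. Dense windows were the 19 of 3033 windows of 1 Mb at or above the 99th percentile of both vehicle H3K9me3 and vehicle H3K27me3. Pol II windows were 100 kb wide and counted positions of height 10 or more. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

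The share and height measures were tested on simulated data built from the Pol II vehicle list of 23765 positions. True shares of 20.3%, 50.3% and 79.6% were recovered as 23.5%, 53.3% and 81.4%, with 2.22% expected at random in the first, and a height ratio of 1.5 was recovered as 1.49. Unshared positions were placed at random, and all shared heights were scaled alike without noise. Pairs were limited by vehicle height and not by mean height. The simulation therefore does not cover clustered treatment-only positions or scatter in height.

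The named positions follow a rule fixed before the data were examined. It takes, for FAIRE, Pol II and H3K4me1, the 3 tallest E2-only and the 3 tallest vehicle-only positions, and the 3 tallest of each other assay. The text gives the tallest of each set and summarises the rest. Chromosomes are named where their density or their E2 to vehicle ratio was the highest or lowest of an assay. The Pol II windows and the dense windows of the repressive marks were chosen after their values were seen.

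Alternatives set before the data were examined were merging within 1 kb, height thresholds, reciprocal overlap of at least 50%, equal list lengths and circular shifts. Those added later were all chromosomes for H3K4me3, leaving out the dense windows and a mean height of 15 or more. The 1 bp overlap, the rule first set, became an alternative when positions within 1 kb were made the main rule, which was decided after the files were seen. In the H3K4me3 lists, chromosomes 20, 21 and X were left out of the comparisons, except the alternative with all chromosomes, the totals stated as such and the counts of the 100 kb windows, because positions named 20 and 21 lie beyond the ends of these chromosomes in the other lists. Gene start sites and gene lists were planned but not run, since only a gene table of another build was at hand and coordinates were not converted. The estrogen receptor binding sites of the same study are not analysed here.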

Results

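The series followed chromatin in MCF-7, a human breast cancer cell line that carries the estrogen receptor, after addition of estradiol (E2), the main estrogen. Cells were kept for 72 h in medium with 5% hormone-stripped serum and then given E2 at 10 nM, or the solvent alone (vehicle), for 3 h. Each treatment was assayed in 8 ways. FAIRE recovers DNA that is not wrapped in nucleosomes, and chromatin immunoprecipitation was done for RNA polymerase II (Pol II), for the histone marks H3K4me1, H3K4me3, H3K9ac and H3K14ac, which the study counts as activating, and for H3K9me3 and H3K27me3, which it counts as repressive. This gave 16 libraries, with 1 library per assay and treatment. No replicates exist, so no difference between E2 and vehicle below can be set against a replicate spread, and no p-value is given.

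Each library is a list of positions in the human genome (build hg18), each with a peak height assigned by the authors. The intervals were short, with medians of 7 to 17 bp, so they mark the tops of peaks. Heights ran from 7 to 200. The number of sequenced reads behind a list is unknown. Binomial (Clopper-Pearson) 95% intervals below cover counting error only. No annotation of this build was used, so positions are given by coordinate and not by gene.

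Pol II had more listed positions after E2, and taller ones. The E2 list held 31129 Pol II positions and the vehicle list 23765, a ratio of 1.31 (95% interval 1.29 to 1.33). At a height of 30 or more, there were 4571 positions after E2 and 1984 in vehicle cells. H3K4me1, a mark of enhancers and promoter flanks, went the other way in number, with 54795 positions after E2 and 74775 in vehicle cells (ratio 0.73, 0.72 to 0.74), yet 3396 of the E2 positions and 1895 of the vehicle positions reached a height of 30. FAIRE had somewhat fewer positions after E2, 12691 against 13763 in vehicle cells (ratio 0.92, 0.90 to 0.94).

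The remaining marks had longer E2 lists. H3K4me3, found at active promoters, had 28068 positions after E2 and 24281 in vehicle cells outside chromosomes 20, 21 and X, whose names are doubtful in these lists, and 31484 and 27605 on all chromosomes. The acetylation marks gave 40025 against 37700 positions for H3K9ac and 35218 against 30360 for H3K14ac. The repressive marks differed by larger factors, with 21111 against 15600 positions for H3K9me3 and 21893 against 14856 for H3K27me3. List lengths also move with sequencing depth and with the threshold of the peak caller, neither of which is known here.

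**Figure D1:**
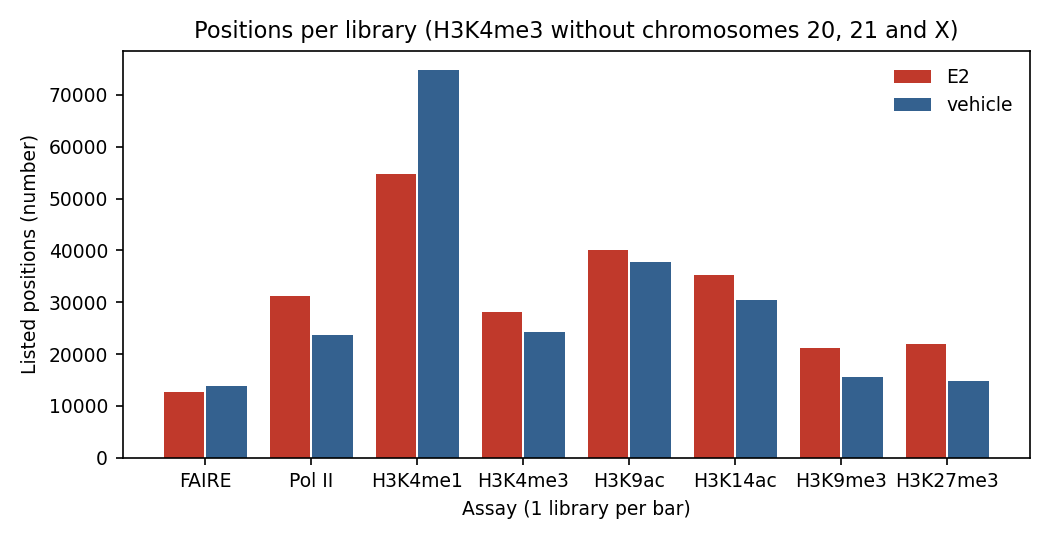
Number of listed positions (vertical axis, from 0) for each assay (horizontal axis), with 1 bar per library, red for E2 and blue for vehicle. H3K4me3 is counted without chromosomes 20, 21 and X. H3K4me1 has the longest lists, 54795 positions after E2 and 74775 in vehicle cells, and Pol II rises from 23765 to 31129.

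Tall positions were shared between treatments more often than low ones. Counting positions within 1 kb of each other as shared, 76.1% of the vehicle Pol II positions (75.6 to 76.7%) had a partner in the E2 list, and 58.3% of the E2 positions had one in the vehicle list. For H3K4me3, 79.1% of the vehicle and 70.0% of the E2 positions were shared, and for H3K9ac 73.4% and 69.0%. FAIRE shared 51.1% of its E2 and 47.1% of its vehicle positions, and H3K4me1 59.4% and 44.1%. H3K9me3 shared 41.3% of its E2 and 55.2% of its vehicle positions, and H3K27me3 37.6% and 54.6%. At equal list lengths H3K9me3 (47.2% and 47.9%) came close to FAIRE (49.0% and 48.8%). Positions placed at random within their chromosomes reached 1.40% to 5.95%. By the overlap of at least 1 bp set before the data were examined, 8.37% of the E2 and 10.97% of the vehicle Pol II positions were shared, since most tops in the 2 lists lie some base pairs apart.

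At heights of 30 to 200, 98.2% of the E2 and 98.3% of the vehicle Pol II positions were shared, and 98.0% of the H3K4me3 positions in either list. H3K4me1 reached 82.2% and 79.9% in this class, the lowest of the 8 assays. At heights of 7 to 9 the shares were 28.8% and 54.4% for Pol II, and 48.5% and 31.5% for H3K4me1.

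**Figure D2:**
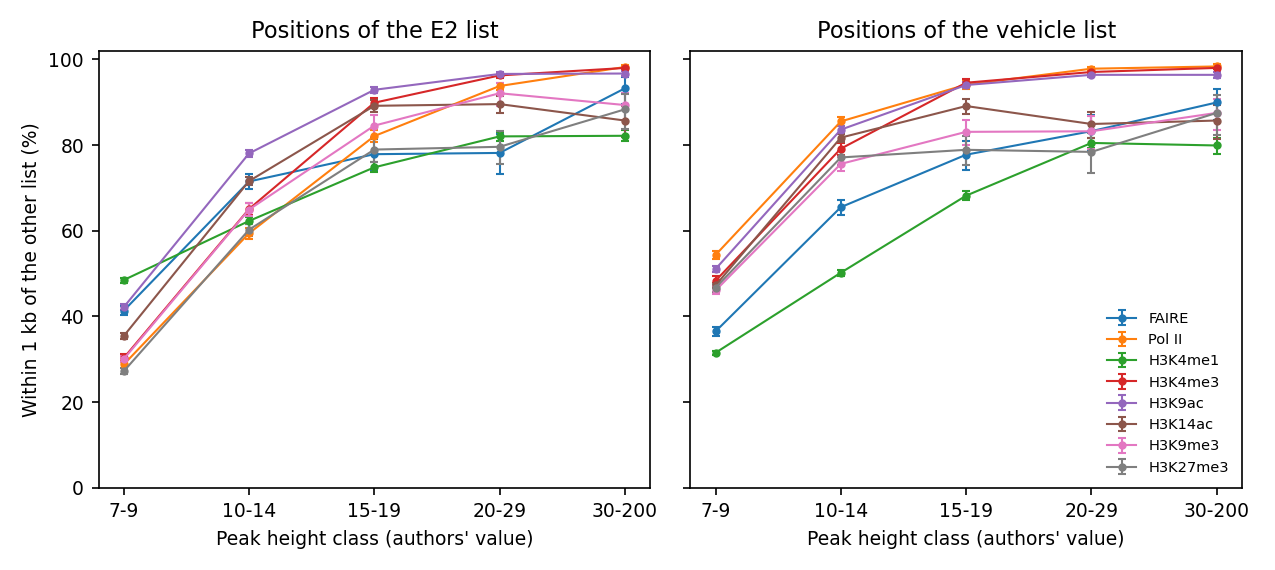
Share of positions with a position of the other treatment within 1 kb (vertical axis, percent) by class of peak height (horizontal axis), for the E2 list (left) and the vehicle list (right), with 1 line per assay and bars for the 95% Clopper-Pearson interval. Pol II rises from 28.8% at heights of 7 to 9 to 98.2% at 30 to 200 in the E2 list.

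At shared positions, Pol II was taller after E2 and H3K4me3 was not. Over 17221 pairs of Pol II positions matched 1 to 1, the median log2 ratio of E2 to vehicle height was 0.36. Over the 8755 pairs with a mean height of 15 or more it was 0.49 (0.47 to 0.50), and 85.3% of these positions were taller after E2. H3K9ac gave 0.25 and H3K14ac 0.18 above this height, H3K9me3 0.14 and H3K27me3 0.13, while H3K4me3 gave -0.06 and FAIRE -0.03. At a reciprocal overlap of 50%, without a limit on height, the median was 0.18 for Pol II, 0.0875 for H3K9ac and 0.10 for H3K9me3, and 0 for H3K14ac and for H3K27me3. H3K4me1 had a median of 0 over all 29371 pairs and of 0.45 over the 7881 tall pairs, with the widest scatter of the assays (SD 0.88 across positions), and 18.9% of the tall pairs lay 2-fold or more below that median. The heights carry no stated scaling between libraries, so these medians describe the lists and not absolute occupancy.

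The E2 list of Pol II was the longer one on every chromosome, by a ratio of 1.11 to 1.47. The stretches described next were chosen after their values were seen, from the 100 kb windows with the largest difference in Pol II positions of height 10 or more. The largest gain lay on chromosome 2 at 11600 to 11700 kb, with 21 such positions after E2 and 1 in vehicle cells. Chromosome 8 at 129100 to 129200 kb had 20 and 4. Next came windows inside the 1 Mb windows dense in the repressive marks, such as chromosome 17 at 57000 to 57100 kb with 33 and 18 and chromosome 20 at 45600 to 45700 kb with 27 and 14. Outside these, chromosome 16 had 17 and 5 at 84100 to 84200 kb and 21 and 9 at 87300 to 87400 kb, and chromosome 7 had 21 and 10 at 156100 to 156200 kb. Across 11500 to 11800 kb of chromosome 2, Pol II had 45 positions of any height after E2 and 17 in vehicle cells, H3K9ac 54 and 35, H3K14ac 28 and 15, and H3K4me3 15 and 9, while H3K4me1 had 43 and 68. H3K27me3 had none in either library there. Across 129000 to 129300 kb of chromosome 8, Pol II had 86 and 40, H3K14ac 68 and 55, H3K9ac 50 and 52, and H3K4me1 46 and 83. H3K4me1 did not go one way at such windows, as positions of height 10 or more numbered 31 after E2 and 20 in vehicle cells in the first of the chromosome 16 windows and 27 and 15 in the second. It was higher after E2 in 33 and lower in 57 of the 95 windows that gained 5 or more such Pol II positions. Of the 36 that lost as many, it was higher in 11 and lower in 21. Its mean difference, E2 minus vehicle, was -3.25 positions in the 95 windows and -0.40 in the other windows. In the 95 windows H3K9ac was higher in 41 and lower in 33, and H3K14ac higher in 47 and lower in 28. H3K4me3 was higher in 36 and lower in 18 of the 83 windows counted for it.

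The largest loss lay on chromosome 13 at 22600 to 22800 kb. Pol II had 2 positions there after E2 and 41 in vehicle cells. H3K4me3 had 1 position there after E2, of height 52, and 3 in vehicle cells, the tallest of height 62, and the tallest H3K9ac position had a height of 31 in each.

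**Figure D3:**
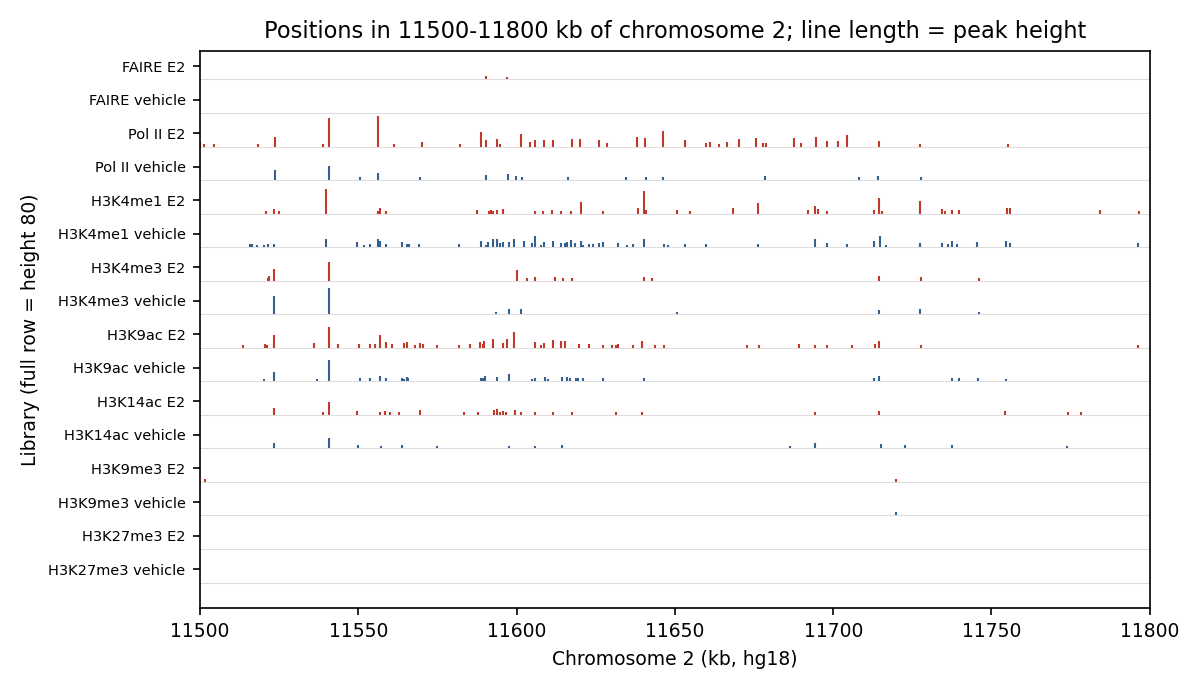
Listed positions across 11500 to 11800 kb of chromosome 2 (horizontal axis, hg18), with 1 row per library and line length proportional to peak height (a full row is 80), red for E2 and blue for vehicle. Pol II has 45 positions after E2 and 17 in vehicle cells, with 25 and 6 of them in 11600 to 11700 kb and 15 and 8 in 11500 to 11600 kb.

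FAIRE positions were sorted into classes with H3K4me3 taken first, whatever else lay nearby, so the size of its class depends on that order. Before sorting, on all chromosomes, 55.3% after E2 and 51.9% in vehicle cells lay near Pol II, and 53.2% and 54.6% near H3K9ac. Of the FAIRE positions, 49.3% after E2 and 46.5% in vehicle cells lay within 1 kb of H3K4me3, 20.3-fold and 21.03-fold over random placement. Pol II lay near 84.6% of these E2 positions and 83.9% of the vehicle ones. FAIRE positions near H3K4me1 but not H3K4me3, the arrangement known from enhancers, made up 12.5% (11.9 to 13.1%) after E2 and 19.6% (18.9 to 20.3%) in vehicle cells, beside H3K4me1 lists of 54795 and 74775 positions. Pol II lay near 42.6% of this class after E2 and 33.7% in vehicle cells. No mark and no Pol II was listed within 1 kb of 20.2% and 19.6% of FAIRE positions.

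The activating marks and Pol II lay together. H3K9ac was within 1 kb of 71.6% of H3K4me3 positions after E2 and of 72.0% in vehicle cells, 23.7-fold and 24.5-fold over random placement. It was also near 60.9% and 69.0% of Pol II positions. H3K4me3 was near 27.2% of H3K4me1 positions after E2 and 16.4% in vehicle cells. H3K27me3 positions were near H3K4me3 in 17.6% of cases after E2 and 21.7% in vehicle cells, 7.62-fold and 10.2-fold over random placement. Enrichment was not particular to the activating marks. FAIRE was 8.73-fold and 11.3-fold enriched near H3K9me3, and 7.82-fold and 6.53-fold near H3K4me1. H3K9me3 was 5.88-fold and 9.66-fold enriched near H3K14ac, and 5.42-fold and 8.56-fold near H3K4me3. It was less enriched near H3K9ac, at 2.51-fold and 4.48-fold. These last values fell to 1.54-fold and 3.03-fold without 19 windows of 1 Mb that were dense in the repressive marks. Those windows held 19.8% and 18.7% of the FAIRE positions and 14.5% and 22.2% of the H3K9me3 positions. The other folds with H3K9me3 were not recomputed without them, so how far they hold outside these windows is unknown.

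**Figure D4:**
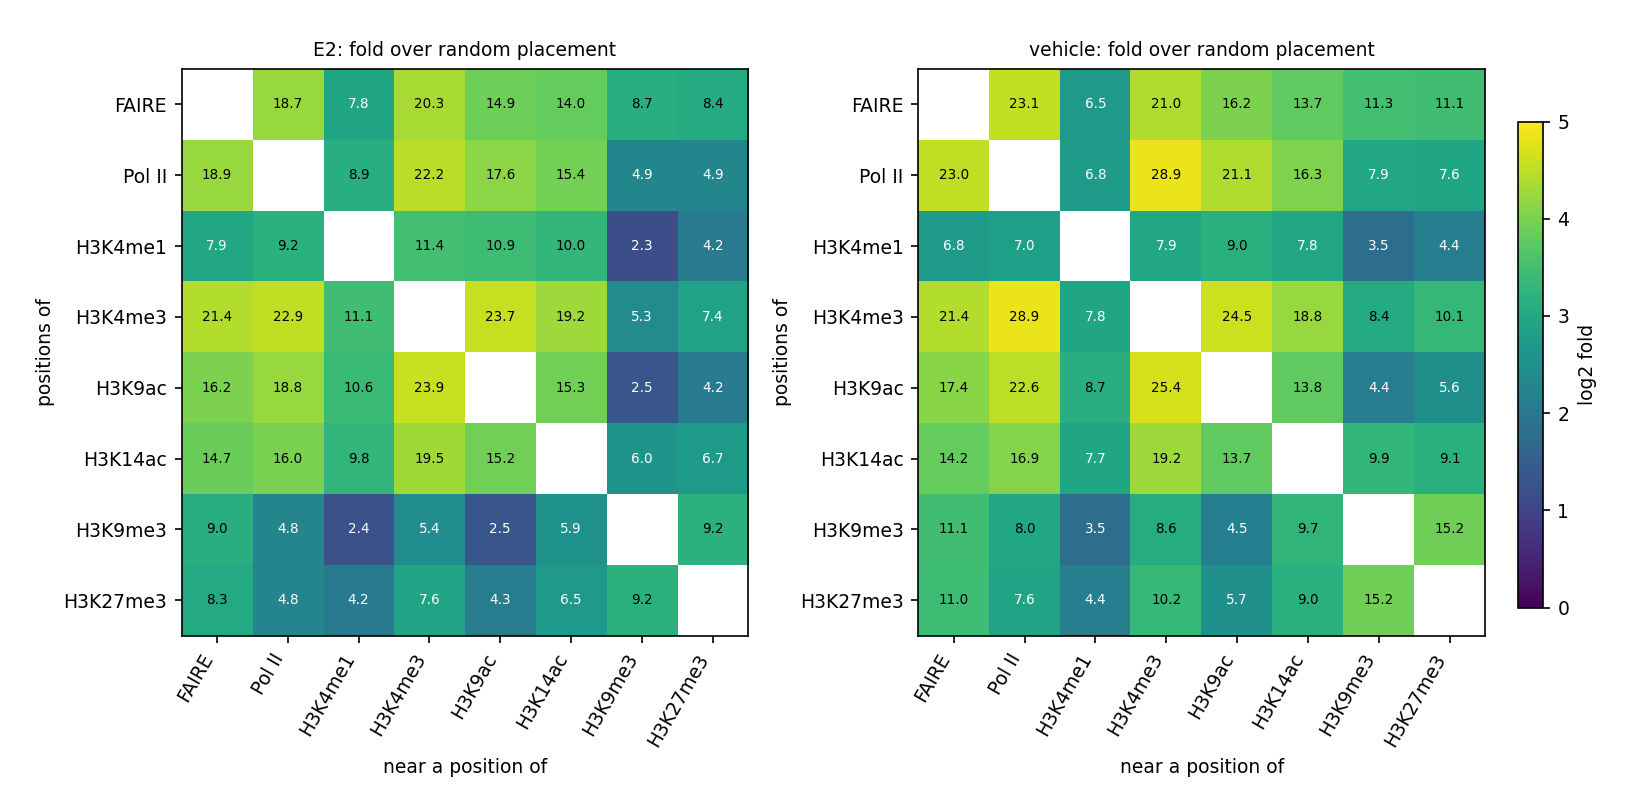
Fold enrichment over random placement of the positions of one assay (rows) within 1 kb of those of another (columns), after E2 (left) and in vehicle cells (right), with color on a log2 scale. H3K4me3 with H3K9ac reaches 23.7-fold and 24.5-fold, and H3K9me3 with H3K9ac 2.51-fold and 4.48-fold.

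Where H3K4me3 was listed after E2 only, a nearby treatment-specific H3K4me1 position was mostly listed in vehicle cells only. Vehicle-only H3K4me1 positions lay near E2-only H3K4me3 positions in 1841 cases and near vehicle-only ones in 678. E2-only H3K4me1 positions lay near vehicle-only H3K4me3 in 1130 cases and near E2-only H3K4me3 in 679. On all chromosomes, 22259 H3K4me1 positions were E2-only and 41794 vehicle-only, so a vehicle-only majority follows in part from list length. The odds ratio for the same direction was 0.22 (block-bootstrap 95% interval 0.17 to 0.28), the lowest of 28 pairs of assays. Treatments were taken from the sample titles, and swapped titles of the H3K4me1 pair would invert this ratio. They would also invert the ratios of H3K4me1 with H3K9me3, 1.38 (1.19 to 1.65), and with H3K27me3, 1.25 (1.04 to 1.46), which lie above 1, and with Pol II, 0.83 (0.74 to 0.92), which lies below 1. Pairs among H3K4me3, H3K9ac and H3K14ac went the same way, at 1.46 for H3K4me3 with H3K9ac, 1.59 for H3K4me3 with H3K14ac and 1.39 for H3K9ac with H3K14ac, but fell to 1.02, 1.03 and 1.02 when treatment-only meant no 1 bp overlap. Such agreement was not particular to activating marks, as H3K14ac with H3K9me3 gave 1.45 (1.20 to 1.75) within 1 kb.

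Pol II went weakly with H3K9ac, H3K4me3 and H3K14ac in the same measure. Its odds ratio was 1.23 (1.04 to 1.48) with H3K9ac, 1.23 (1.01 to 1.46) with H3K4me3, 1.18 (1.04 to 1.38) with H3K14ac and 0.83 (0.74 to 0.92) with H3K4me1. FAIRE gave 0.99 (0.83 to 1.22) with Pol II, and its interval included 1 with each other assay. The intervals describe spread along the genome within these libraries, and they say nothing of other cultures. With treatment-only positions defined by the absence of a 1 bp overlap, the ratio for H3K4me1 with H3K4me3 was 0.85 and the 3 ratios of Pol II with H3K9ac, H3K4me3 and H3K14ac lay between 1.00 and 1.02.

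**Figure D5:**
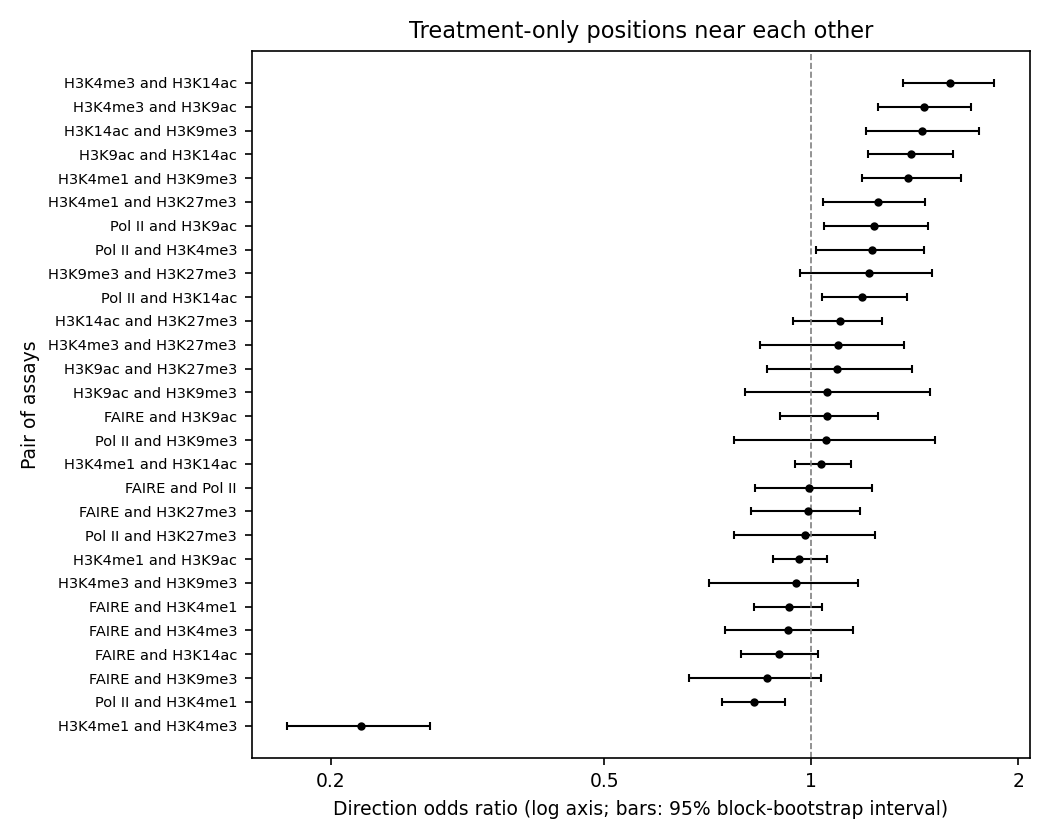
Odds ratio (horizontal log axis) that treatment-only positions of a pair of assays within 1 kb belong to the same treatment, for 28 pairs (vertical axis), with bars for the 95% block-bootstrap interval and a dashed line at 1. H3K4me1 with H3K4me3 stands apart at 0.22, and the highest is H3K4me3 with H3K14ac at 1.59.

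H3K9me3 was dense on chromosomes 19 and 20 after E2. Both held close to the same number of H3K9me3 positions per Mb after E2, 28.3 on chromosome 19 and 28.2 on chromosome 20, against a median of 5.67 over the chromosomes. In vehicle cells the density was 15.8 on chromosome 19 and 28.3 on chromosome 20. Chromosome 20 held several of the 19 dense windows, which were dense in other assays too. Of its 1763 H3K9me3 positions after E2 and 1767 in vehicle cells, 362 and 365 lay at 52 to 53 Mb. The window at 46 to 47 Mb held 212 and 320. FAIRE had 176 and 183 positions in the former window and 291 and 293 in the latter. The ratio of E2 to vehicle positions was 1.79 on chromosome 19, close to the 1.77 of chromosome 6. The distal long arm of chromosome 19, 57 to 64 Mb, a stretch known for clusters of zinc finger genes, held 754 H3K9me3 positions after E2 and 466 in vehicle cells. These were 41.8% and 46.3% of the H3K9me3 positions of the chromosome. FAIRE had 46 and 54 positions there. H3K27me3 had 207 and 109 positions in the same stretch, 32.6% and 28.5% of its positions on the chromosome. The window at 57 to 58 Mb, picked after its values were seen, had 238 and 134 H3K9me3 positions beside 2 and 1 of H3K27me3.

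H3K27me3 outnumbered H3K9me3 in other windows, also picked after their values were seen. Chromosome 16 at 81 to 82 Mb held 190 H3K27me3 positions after E2 and 111 in vehicle cells, beside 49 and 22 of H3K9me3 and 2 FAIRE positions in each library. Chromosome 15 at 51 to 52 Mb, one of the 19 dense windows, held 195 and 148, beside 73 and 56 of H3K9me3 and 1 and 2 FAIRE positions.

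Chromosome 20 carried the highest density of vehicle positions in every assay except H3K4me3, for which it was left out. FAIRE had 20.7 vehicle positions per Mb there against a median of 3.67 over the chromosomes, and H3K4me1 74.0 against 24.9. Part of this lay in the dense windows, as 46 to 47 Mb held 293 of the 1295 vehicle FAIRE positions of the chromosome. X had the lowest vehicle density for Pol II, H3K4me1, H3K9ac, H3K14ac, H3K9me3 and H3K27me3, and chromosome 13 for FAIRE and H3K4me3. The E2 to vehicle ratio for H3K4me1 was highest on chromosome 19, at 0.97, and lowest on chromosome 3, at 0.63. For Pol II it was highest on chromosome 21, at 1.47, and lowest on chromosome 13, at 1.11.

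The tallest treatment-only positions lay mostly in stretches that were dense in both treatments. Of the 6 positions named for each assay, 5 for FAIRE, 4 for Pol II and 6 for H3K4me1 lay in the 19 dense windows. The tallest E2-only Pol II position was on chromosome 16 at 44944422 to 44944423, with a height of 170, and the tallest vehicle-only one lay 2875 bp away at 44947297 to 44947298, with a height of 177. That these 2 count as treatment-only rests on the 1 kb limit, and H3K9me3 reached 200 in both libraries near the first. The tallest E2-only FAIRE position, on chromosome 20 at 45421441 to 45421442, had a height of 56, and H3K9ac nearby reached 116 after E2 and 120 in vehicle cells. The tallest vehicle-only FAIRE position, at 51914075 to 51914083 of chromosome 20, had a height of 62. For H3K4me1 the tallest E2-only position was on chromosome 17 at 56845055 to 56845056 (height 190), and the tallest vehicle-only one on chromosome 20 at 45419494 to 45419495 (height 170). The 1 kb limit matters for these assays too. A vehicle-only FAIRE position of height 57 lay at 45419799 to 45419801 of chromosome 20, just outside the limit from the E2-only one. So did a vehicle-only H3K4me1 position of height 152 at 56843661 to 56843663 of chromosome 17.

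Among the other assays, the tallest H3K9ac position lay on chromosome 20 at 48781639 to 48781640, with a height of 187 after E2 and 179 for its neighbor in vehicle cells. H3K4me3 was tallest, outside chromosomes 20, 21 and X, on chromosome 1 at 154452995 to 154452996, at 195 after E2. H3K14ac reached 182 on chromosome 18 at 98287 to 98288, H3K9me3 200 on chromosome 16 at 44944347 to 44944348, and H3K27me3 190 on chromosome 10 at 41705086 to 41705087, where FAIRE also reached 189 and 188. The chromosome 18 and chromosome 1 positions were tall in other assays as well. On chromosome 18, FAIRE reached 139 and 140, H3K4me3 189 and 186, and H3K9me3 200 in both libraries. On chromosome 1, H3K9me3 reached 195 and 187 and H3K27me3 105 and 91.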

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

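The tests named here as chosen after the result was seen are the Pol II height comparison limited to mean heights of 15 to 50, the count of windows above 20% and the joint direction of H3K4me1 number and heights. The last of these is fixed by the pattern, so its value is printed but not weighed. FAIRE density in the dense windows as a test of extra copies, the share of taller Pol II positions as a test of enrichment and the number of H3K4me1 positions by itself as a test of depth were dropped because the pattern fixes their outcome. The tests of extra copies by neighboring windows and of depth by H3K4me1 heights took their place, set before their own values were seen but after the patterns were. The bounds for pile-ups and for Pol II depth were altered after their values were seen and then restored as first set, and the reading of pile-ups on repeats changed and changed back with them.

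Positions outside the main comparisons carried signal under a doubtful chromosome name. In the H3K4me3 lists, 53 positions after E2 and 232 in vehicle cells were named chromosome 20 but lay beyond the end of that chromosome in every other list, as did 4 and 5 positions named chromosome 21. Read as X, the positions named 20 fell within 1 kb of an H3K9ac position on X in 88.7% of cases after E2 and 83.2% in vehicle cells, against 1.06% and 0.87% for random placement. Positions of these lists named 20, 21 or X were therefore left out of the main comparisons.

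H3K4me1 had fewer positions after E2 but more of height 30 or more, at a median height of 9 in both lists, and its treatment-only positions ran against those of H3K4me3. At a fixed threshold, a deeper E2 library would list more positions above the same lowest height of 7, while the ratio was 0.73. This restates the pattern, and the threshold of the peak caller is unknown, so it cannot decide on a depth difference alone. Depth also stays open for the height by itself. At mean heights of 15 to 50, the median log2 height ratio of H3K4me1 was 0.44 at H3K9ac positions (n = 1948). It was 0.50 (0.25 to 0.75, n = 86) at positions in all FAIRE, H3K9me3 and H3K27me3 libraries, a difference of -0.0674. A bias along the genome may explain part of the pattern. Over 1 Mb windows, the E2 share of H3K4me1 positions followed H3K9ac density. The Spearman rho was 0.38 even for positions over 5 kb from H3K4me3, which argues against an effect at promoters alone. An effect of E2 that varies along the genome would give such a gradient too, so rho cannot tell it apart from a bias along the genome. The odds ratio pooled within classes of H3K9ac density stayed at 0.23 (0.18 to 0.29), which argues against such a bias as the source of the opposite direction to H3K4me3. Swapped treatment labels of the H3K4me1 pair would invert that ratio, and also those with H3K9me3 (1.38) and H3K27me3 (1.25), which lie above 1, and with Pol II (0.83), which lies below, and no value here decides it, while an exchange of H3K4me1 for H3K4me3 after E2 is a hypothesis left untested. Of all H3K4me3 positions, 45.1% after E2 and 42.7% in vehicle cells lay within 1 kb of H3K4me1, so this share was no lower after E2.

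The 19 windows dense in vehicle H3K9me3 and H3K27me3 held, at the median window, 13.2 to 45.7 times the genome median in the lists of the other assays. The genome median here is taken over windows with at least 1 position. For H3K4me3 the values were 9.38 and 12.6 times, over the 12 windows outside chromosomes 20 and 21. However, chromosome 15 at 51 to 52 Mb had only 1 and 2 FAIRE, 14 and 6 Pol II and 10 and 6 H3K9ac positions. Chromosome 21 at 10 to 11 Mb had 15 and 20 of H3K9ac. Pile-ups confined to a few narrow blocks, which need under 20% of the 10 kb bins of a window, are argued against by a median of 72% of bins with a FAIRE position (62% for H3K9me3) and over 20% in 17 of the 19 windows, although the lower quartile of 48% fell short of the 50% set beforehand. Extra copies of these stretches, known in MCF-7 on parts of several chromosomes, cannot be told apart from pile-ups on repeats, because the 21 windows next to them held a median of 4.67 times the genome median of FAIRE positions after E2 but a lower quartile of 0.333 times. Pile-ups on repeats stay open, as FAIRE positions of height 30 or more were 3.28 (E2) and 4.06 (vehicle) times as frequent in the dense windows as elsewhere, past the first bound of 2 times, but extra copies would raise heights too, and the ratios for H3K27me3 (2.41 and 1.16) and H3K9me3 (1.22 and 0.625) are not weighed because the windows were chosen on these marks. No biological explanation was tested, since no group of the design bears on copy number.

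Pol II had more and taller positions after E2. Greater depth of the E2 library would raise all positions alike, but the median log2 height ratio at H3K4me3 positions (0.50, n = 3222) exceeded that at positions listed in all FAIRE, H3K9me3 and H3K27me3 libraries (0.08, n = 189) by 0.42, and by 0.44 at mean heights of 15 to 50. This comparison was repeated at those heights because the tallest positions lie near the ceiling of 200. A stronger enrichment in the E2 immunoprecipitation and an effect of E2 on Pol II both stay open, untested, with 1 library per treatment.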

How the results depend on the processing

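The alternatives chosen after the data were seen are all chromosomes for H3K4me3, leaving out the dense windows and a mean height of 15 or more, while the 1 bp overlap was the rule set before and became an alternative when 1 kb was made the main rule after the files were seen. Of the recomputed values with an interval, 40 stayed within it, 153 left it and 5 changed the side of 1, and the count of pairs of assays with an odds ratio above 1 went from 17 to 20 and 15. Merging positions within 1 kb kept all 8 ratios of list lengths within their intervals, and the longer list of each assay came from the same treatment after merging and above the median height. Every fold over random placement stayed above 1 in the settings run. The 1 bp and reciprocal overlaps leave few shared positions by construction, since tops are narrower than the distance between lists, and treatment-only positions then hold most of each list. The cause was not tested for the other shifts. No paired analysis was possible because each group has 1 library. The unknown depth limits what the low heights can show. Gene start sites and gene lists, and their alternatives, were not run.

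At a 1 bp overlap the shared percentages of the E2/vehicle lists fell to 10.1/9.34 for FAIRE, 8.37/10.97 for Pol II, 5.35/3.92 for H3K4me1 and 5.72/6.61 for H3K4me3. The later marks gave 5.64/5.99 for H3K9ac, 6.51/7.55 for H3K14ac, 6.75/9.13 for H3K9me3 and 5.85/8.62 for H3K27me3. A reciprocal overlap of 50% left 3.67/3.39 for FAIRE, 2.25/2.95 for Pol II, 1.09/0.798 for H3K4me1 and 1.75/2.03 for H3K4me3. It left 1.43/1.52 for H3K9ac, 1.79/2.08 for H3K14ac, 3.12/4.22 for H3K9me3 and 2.83/4.17 for H3K27me3. Lists of equal length gave 49.0/48.8 for FAIRE, 69.1/70.4 for Pol II, 51.2/50.02 for H3K4me1 and 77.2/76.2 for H3K4me3. Among the rest were 71.4/71.9 for H3K9ac, 53.2/53.5 for H3K14ac, 47.2/47.9 for H3K9me3 and 45.3/46.1 for H3K27me3. The taller part of each list, from its median height up, raised the shares to 61.1/56.8 for FAIRE, 84.5/93.6 for Pol II, 67.7/54.9 for H3K4me1 and 96.2/97.46 for H3K4me3. This also gave 92.03/90.9 for H3K9ac, 61.0/69.5 for H3K14ac, 52.7/66.4 for H3K9me3 and 48.7/66.0 for H3K27me3. Without the dense windows, shares that moved were 45.8 (vehicle only) for FAIRE, 77.9 (vehicle only) for Pol II, 58.9 (E2 only) for H3K4me1 and 80.1 (vehicle only) for H3K4me3. Others moved to 74.1 (vehicle only) for H3K9ac, 47.0/55.6 for H3K14ac, 36.8/53.6 for H3K9me3 and 33.0/51.5 for H3K27me3. Keeping all chromosomes, the vehicle H3K4me3 share was 77.8%. Folds over random placement at a 1 bp overlap were 98.6/119 for FAIRE near Pol II, 23.6/13.5 for FAIRE near H3K4me1, 118/116 for H3K4me3 near H3K9ac and 33.2/37.5 for Pol II near H3K9ac. Beyond these came 26.0/36.0 for H3K27me3 near H3K9ac, 17.4/32.9 for H3K9me3 near H3K9ac and 65.2/95.6 for H3K27me3 near H3K4me3. Between the taller parts of both lists the folds were 29.03/33.8 for FAIRE near Pol II, 9.18/8.09 for FAIRE near H3K4me1, 54.9/59.5 for H3K4me3 near H3K9ac and 42.0/45.9 for Pol II near H3K9ac. Further folds were 5.83/7.54 for H3K27me3 near H3K9ac, 3.30/5.94 for H3K9me3 near H3K9ac and 8.61/10.7 for H3K27me3 near H3K4me3. With the dense windows left out the folds were 24.9/31.3 for FAIRE near Pol II, 9.26/7.49 for FAIRE near H3K4me1, 25.7/26.9 for H3K4me3 near H3K9ac and 20.7/25.6 for Pol II near H3K9ac. Remaining folds were 4.02/5.43 for H3K27me3 near H3K9ac, 1.54/3.03 for H3K9me3 near H3K9ac and 9.73 (vehicle only) for H3K27me3 near H3K4me3. Circular shifts moved the folds to 22.7 (vehicle only) for FAIRE near Pol II and 7.9998 (E2 only) for FAIRE near H3K4me1. All chromosomes moved the folds to 23.9/24.1 for H3K4me3 near H3K9ac and 8.46/10.8 for H3K27me3 near H3K4me3.

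Counting only positions at or above the median height, the E2 to vehicle ratio of positions was 0.886 for FAIRE, 0.764 for H3K4me1, 1.11 for H3K4me3, 1.08 for H3K9ac, 1.24 for H3K14ac, 1.38 for H3K9me3 and 1.55 for H3K27me3. The median log2 height ratio at a mean height of 15 or more was -0.0287 for FAIRE, 0.49 for Pol II, 0.45 for H3K4me1, -0.0589 for H3K4me3, 0.25 for H3K9ac, 0.18 for H3K14ac and 0.14 for H3K9me3. At a reciprocal overlap of 50% it was 0.18 for Pol II, 0.17 for H3K4me1, 0.0875 for H3K9ac, 0 for H3K14ac, 0.10 for H3K9me3 and 0 for H3K27me3. Direction odds ratios with treatment-only positions defined at 1 bp moved to 0.919 for Pol II with H3K4me1, 1.01 for Pol II with H3K9ac, 1.00 for Pol II with H3K14ac, 0.851 for H3K4me1 with H3K4me3, 1.02 for H3K4me3 with H3K9ac, 1.03 for H3K4me3 with H3K14ac and 1.02 for H3K9ac with H3K14ac. The side of 1 changed for FAIRE with Pol II (1.01) and Pol II with H3K27me3 (1.01), whose intervals within 1 kb include 1. For the taller treatment-only positions they moved to 0.725 for Pol II with H3K4me1, 1.504 for Pol II with H3K4me3 and 1.48 for Pol II with H3K14ac. The side of 1 changed for FAIRE with Pol II (1.09), Pol II with H3K9me3 (0.989) and Pol II with H3K27me3 (1.18), whose intervals within 1 kb also include 1.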

Other observations

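Some FAIRE positions had a neighbor in every list. Of the FAIRE positions outside chromosomes 20, 21 and X, 123 after E2 and 117 in vehicle cells lay within 1 kb of a position in all 16 lists. Their median heights were 29 and 31, against 8 and 8 for the remaining FAIRE positions. They include the tallest H3K27me3 position, on chromosome 10 at 41705086 to 41705087, where Pol II reached 169 after E2 and 180 in vehicle cells and H3K9me3 191 and 193. At the other end, 1603 FAIRE positions after E2 and 1783 in vehicle cells had no position of any other assay within 1 kb in either treatment.

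The E2 share of H3K9me3 positions fell with H3K9ac density along the genome (Spearman rho -0.42 over 321 windows), and that of H3K27me3 did as well (rho -0.34 over 362 windows). Without the dense windows, a setting chosen after the data were seen, the values were -0.39 over 309 windows and -0.31 over 350.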
